A study of Caenorhabditis elegans with 4 samples.

How the data were processed

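Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to locate the genomic binding of UNC-39 in Caenorhabditis elegans hermaphrodites at the L2 larval stage. UNC-39 is a SIX-family homeodomain transcription factor. Worms of strain OP186 carried an unc-39 transgene fused to EGFP together with an unc-119 rescue marker, and they were raised at 20 °C. Per the labels' protocols, worms were crosslinked with 2% formaldehyde, chromatin was sonicated, and tagged protein with its DNA was collected with affinity-purified goat anti-GFP antibody. A 10% portion of each lysate was kept as input DNA. The labels give 4 samples, 2 ChIP libraries and 2 input libraries, each numbered replicate 1 and 2. Nothing in the labels says whether the replicates came from separate worm cultures, so agreement between them may be partly technical.

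Peak lists were analysed for ChIP replicate 1, for ChIP replicate 2 and for a combined set, and no values of the input libraries were analysed here. Peaks were called with PeakSeq and placed on WormBase genome WS180, per the file headers and the source column of the files. PeakSeq is a program that finds regions where ChIP reads exceed a control. The deposited value of each peak is a q value from the authors' peak caller, which is a p-value adjusted for multiple testing, with a low q for a strong peak. The aligner, software versions, read filters, q threshold, the control used for each list and the way the combined list was built are not given in the sources used here. Read counts and sequencing depths are unknown, so peak strength could be compared only through q values and peak widths, and a difference in list length between replicates cannot be separated from a difference in depth. The largest q in each list differed, so the lists were also compared at a common q. Positions are 1-based and inclusive.

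Everything else was computed from the deposited starts, ends and q values with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and Matplotlib 3.10.9. Peaks were ranked by q. Peaks of different lists were called shared when they overlapped by at least 1 bp. The number shared was compared with 10000 random placements of the replicate 1 peaks on their own chromosomes with widths kept (one-sided permutation test). Medians of −log10 q and width were compared by a two-sided permutation test with 100000 resamples. Shares carry 95% exact Clopper-Pearson intervals, which cover counting error over peaks only. The count on each of 6 nuclear chromosomes was tested by a two-sided exact binomial test with Benjamini-Hochberg adjustment over the 6. Chromosome lengths of WS180 were not used here, so the furthest peak end on each chromosome in any list stood for its length, and slightly understates it. The share of peak midpoints in the middle 50% of each chromosome was tested by the same binomial test. Distances between neighbouring midpoints were compared with 10000 placements of the same number of points on each chromosome (two-sided permutation test). Shares in strong and weak peaks were compared by two-sided Fisher's exact tests. The smallest p that 10000 placements can give is 0.0001 in a one-sided test and 0.0002 in a two-sided test. The smallest that 100000 resamples can give is 1e-05. Peaks are not independent replicates of an experiment, so these tests describe the lists, not the variation between worm populations.

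The tests, the rule for named peaks and 30 of the 43 alternative values were fixed before the data were examined, and the other 13 were chosen after. The rule took the 25 combined peaks of lowest q and the 10 replicate 1 peaks of lowest q. Tests of promoters, gene features, 20 gene lists and sequence motifs had been planned, but they need the gene positions or sequence of WS180, which were not used here. The RefSeq gene table that was used describes assembly WBcel235, and coordinates of the 2 builds were never joined. It served only for gene symbols and for the number of protein-coding genes per chromosome. Peaks are therefore given by position, with no gene assigned. The alternatives were other overlap criteria, the combined peaks of lower q, merging of peaks within 1000 bp, other definitions of the chromosome centre, and each replicate list in place of the combined list. Those chosen after the data were seen were the replicate 2 peaks at or below the largest q of replicate 1, the 41 replicate 2 peaks of lowest q, a q threshold 10 times stricter, the removal of peaks under 50 bp or of chromosome I, expected shares from gene numbers and the count of pairs under 5000 bp. The comparison of shared and other peaks down to rank 173 was also added after the data were examined, though its outcome had not been seen when it was chosen. The count on X in the 100 combined peaks that follow the strongest 100 was chosen after the data were seen. Neither of these is among the 43 alternatives.

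The procedures were tested on simulated data. For the replicate overlap, 20 of 41 peaks were placed on a second list and the rest kept clear of it. The 20 were recovered, which checks only the counting, and 1 of 100 unrelated pairs of lists was called at a threshold of 0.05. For the chromosome test, 49 of 1000 even simulations of 1082 peaks were called on X, and 1000 of 1000 were called with X raised 1.5 times. These counts were drawn from the same binomial distribution that the test assumes. They check only the code, and cannot show whether the p-values hold for peaks that lie close together. For clustering, 3 of 50 even lists and 50 of 50 lists with 200 planted neighbours were called by the median distance. The chromosome simulations did not cover lists of 41 peaks, and the count of close pairs was not simulated.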

Results

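UNC-39 binding sites were mapped in L2 larvae by ChIP-seq against an EGFP tag on the protein. UNC-39 is a SIX-family homeodomain factor with roles in neuronal migration and mesoderm development in this nematode. The ChIP group held 2 libraries and the input group 2. Only peak lists were analysed, so read depth was unknown. The intervals reflect the number of peaks in a list, not the variation between the 2 ChIP libraries. Replicate 1 gave 41 peaks with a median width of 486 bp. Replicate 2 gave 1077 peaks with a median width of 299 bp, and the combined list held 1082 with a median of 301 bp. The lists covered 22.7 kb, 447.5 kb and 451.1 kb of the WS180 genome. The largest q was 5.59e-06 in replicate 1, 5.93e-05 in replicate 2 and 5.90e-05 in the combined list. At or below the largest q of replicate 1, replicate 2 still held 539 peaks, so the difference in list length was present at a common q.

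The first comparison asked which binding sites were found in both ChIP replicates. Nearly every site of replicate 1 was recovered: 40 of 41 peaks overlapped a replicate 2 peak (97.6%, 95% interval 87.1 to 99.9%). Random placement gave 0.516 overlapping peaks on average and 5 at most (one-sided permutation test, p = 0.0001, the smallest p possible). The exception was a peak of 81 bp at II 6175099 to 6175179 with q = 4.62e-06. In the other direction, only 40 of 1077 replicate 2 peaks (3.71%, interval 2.67 to 5.02%) overlapped replicate 1. The random placements were spread evenly along each chromosome. The overlap therefore shows that the same regions were called again, and does not by itself show that UNC-39 bound them.

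The strongest site of replicate 1 lay at IV 14032632 to 14034281 (q = 6.80e-12) and ranked 8 in replicate 2 (q = 4.45e-25). Chromosome X held 6 of the 10 strongest replicate 1 sites. These were X 8036159 to 8036789 (q = 2.88e-10), X 13700628 to 13701017 (q = 3.32e-10), X 11093930 to 11094314 (q = 4.40e-10), X 2996760 to 2997327 (q = 8.35e-10), X 16930943 to 16931679 (q = 1.49e-08) and X 5728886 to 5729749 (q = 1.93e-08). The remaining 3 were III 10758989 to 10759335 (q = 2.81e-09), I 5315910 to 5316881 (q = 2.99e-09) and III 8392232 to 8392593 (q = 2.24e-08). All 10 were found in replicate 2, at ranks between 3 and 33.

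The shared sites were among the stronger sites of replicate 2. Their median −log10 q in replicate 2 was 14.7, against 5.18 for the 1037 peaks that were not shared (two-sided permutation test, p = 1e-05, the smallest p possible). Their median width was 677 bp against 284 bp (permutation p = 1e-05). Replicate 1 contained 7 of the 10 strongest replicate 2 peaks, 27 of the 50 strongest and 36 of the 100 strongest. No shared peak ranked lower than 173. All 40 shared sites had the lower q in replicate 2, and 38 were wider there, with a median width ratio of 1.21. Across the 40 shared peaks, −log10 q was correlated between replicates (Pearson r = 0.58, permutation p = 0.00019, Spearman rho = 0.58, permutation p = 0.00014, both with adjusted p = 0.00019). Without the 2 peaks farthest from the replicate 1 median, r was 0.55. This correlation is across peaks, which are not independent replicates.

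**Figure D1:**
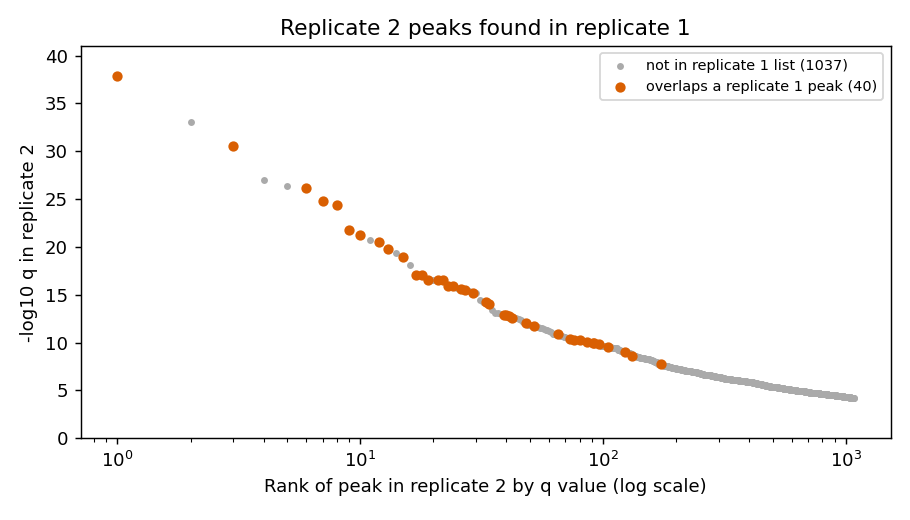
Replicate 2 peaks by rank of q (x axis, log scale) and −log10 q (y axis), each point a peak. The 40 peaks that overlap replicate 1 (orange) all lie at rank 173 or better, among 133 peaks of that rank or better that do not (grey), including ranks 2, 4 and 5. Every peak below rank 173 is absent from replicate 1.

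The combined list was compared with the replicates to see what each contributed. It was close to the replicate 2 list: 1039 of 1082 combined peaks (96.03%, interval 94.7 to 97.1%) overlapped a replicate 2 peak. It also took in 40 of the 41 replicate 1 peaks (97.6%, interval 87.1 to 99.9%), all at sites that replicate 2 had as well. These made up 3.70% of the combined list, a share limited by the length of the replicate 1 list. The 43 combined peaks that overlapped neither replicate were mostly weak, with a median q of 3.29e-05 and a median width of 117 bp, though the strongest ranked 198. Of the 1039 overlapping pairs, 907 (87.3%) carried exactly the replicate 2 q value and 828 (79.7%) had exactly its start and end. The combined list is not independent of the replicate lists, so no test was made between them.

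Among the 25 strongest combined sites, 17 overlapped replicate 1. Chromosome I held 12 of them, X held 9, V held 2, and III and IV held 1 each. The strongest was I 9380854 to 9382030 (1177 bp, q = 1.41e-38), followed by I 5315876 to 5316997 (q = 2.80e-31), and both were also found in replicate 1. Next came I 1834260 to 1837457 (3198 bp, q = 5.57e-29) and I 1067992 to 1070402 (2411 bp, q = 9.45e-28), which were not in the replicate 1 list. The strongest X site was X 13700607 to 13701070 (q = 6.85e-27, also in replicate 1), and the strongest X site absent from replicate 1 was X 10568251 to 10569141 (q = 1.71e-21). Strong sites found in replicate 1 also included I 7474541 to 7475759 (q = 1.67e-25), IV 14032493 to 14034570 (q = 4.45e-25), III 10758970 to 10759406 (q = 1.56e-22) and V 1151280 to 1151964 (q = 1.30e-16).

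The widest site was a 23627 bp interval at V 14364426 to 14388052 (q = 4.64e-27, rank 5), 78.5 times the median width. A 5885 bp peak at V 14391047 to 14396931 (q = 8.06e-08) followed after a gap of 2994 bp. Both intervals had the same ends in replicate 2, and neither overlapped a replicate 1 peak. At the other extreme, 115 combined peaks (10.6%) were narrower than 50 bp and 7 were a single base wide.

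**Figure D2:**
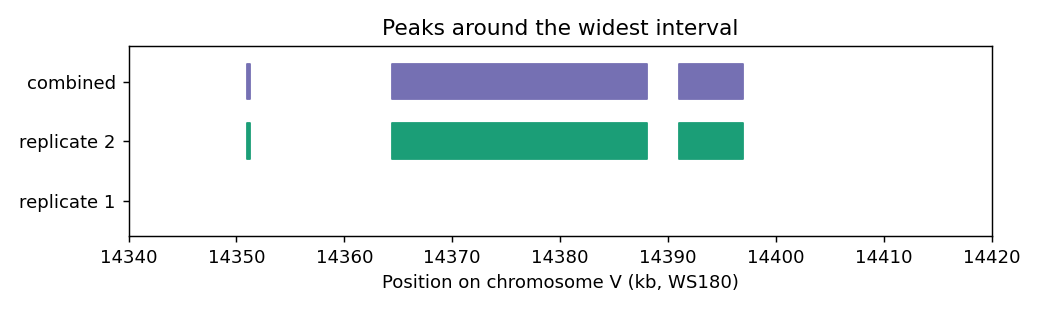
Peaks of the 3 lists (rows) along chromosome V around the widest interval (x axis, position in kb, WS180). The 23627 bp and 5885 bp intervals appear in replicate 2 and in the combined list, and the replicate 1 row has no peak in this window.

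The distribution of sites among the 6 chromosomes was compared with chromosome extent. Chromosome I had the highest density of called peaks. It held 404 of 1082 combined peaks (37.3%, interval 34.4 to 40.3%) on 15.1% of the extent, 2.48 times the expected number (exact binomial test, adjusted p = 6.7e-71). Its density was 26.97 peaks per Mb, against 5.38 to 9.28 on the other 5 chromosomes. Chromosome IV was the sparsest, with 93 peaks (8.60%, against 17.4% of the extent, exact binomial test, adjusted p = 3.67e-16). Chromosomes II (114 peaks, 10.5% against 15.3%, adjusted p = 1.42e-05) and V (185 peaks, 17.1% against 20.9%, adjusted p = 0.00253) were also below expectation, and III (125 peaks, 11.6% against 13.6%, adjusted p = 0.0561) did not pass the exact binomial test. The peaks on I lower every other share. With I left out, a choice made after the data were seen, IV stayed below expectation (13.7% of 678 peaks against 20.5%, exact binomial test, adjusted p = 2.9e-05). The deficit on II did not pass (16.8% against 18%, exact binomial test, adjusted p = 0.453), and V was at 27.3% against 24.7% (exact binomial test, adjusted p = 0.149). Replicate 2 alone put 408 of 1077 peaks (37.9%) on I. In replicate 1, chromosome I held 10 of 41 peaks (24.4%, interval 12.4 to 40.3%), which did not pass the exact binomial test (adjusted p = 0.183). Chromosome V was below expectation in replicate 1, with 1 of 41 peaks (2.44% against 20.9%, exact binomial test, adjusted p = 0.00469), and also with I left out (3.23% of 31 peaks against 24.7%, exact binomial test, adjusted p = 0.00707). At equal list length, a comparison chosen after the data were seen, the 41 strongest replicate 2 peaks included 14 on I (34.1%, interval 20.1 to 50.6%), which passed the exact binomial test (adjusted p = 0.00951), and 6 on V (14.6%, interval 5.57 to 29.2%), where a deficit did not pass (exact binomial test, adjusted p = 0.493). The deficits on II (0 of 41, adjusted p = 0.00951) and IV (1 of 41, adjusted p = 0.0129) passed the exact test there, and a difference on III did not pass it (7 of 41, adjusted p = 0.493). For both I and V the intervals of the replicates overlap at this length.

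Chromosome X held 16 of 41 replicate 1 peaks (39.0%, interval 24.2 to 55.5%), 2.20 times its 17.7% share of the extent (exact binomial test, adjusted p = 0.00469). Replicate 2 had 154 of 1077 peaks on X (14.3%, interval 12.3 to 16.5%, exact binomial test, adjusted p = 0.00331 for a share below expectation) and the combined list 161 (14.9%, interval 12.8 to 17.1%, adjusted p = 0.0163). In the same comparison at equal list length, the 41 strongest replicate 2 peaks included 13 on X (31.7%, interval 18.1 to 48.1%, exact binomial test, p = 0.0376, adjusted p = 0.0564 over 6 chromosomes), which did not pass after adjustment. The intervals of the replicates overlap at this length. With chromosome I left out, the combined share on X was 23.7% against 20.9% expected (exact p = 0.0726, adjusted p = 0.139), so the deficit on X depended on the count on I. Within replicate 2, X carried 16 of the 40 peaks shared with replicate 1 (40%) and 138 of the 1037 others (13.3%, Fisher's exact test, adjusted p = 0.000247 over 6 chromosomes). Limited to the replicate 2 peaks down to rank 173, a choice made after the data were seen, the shares were 40% of 40 and 15.8% of 133 (Fisher's exact test, adjusted p = 0.0116). Chromosome V showed the opposite difference, with 1 of 40 shared peaks (2.50%) and 184 of 1037 others (17.7%, Fisher's exact test, adjusted p = 0.0263). Down to rank 173 the V difference did not pass the test (2.50% of 40 against 16.5% of 133, Fisher's exact test, adjusted p = 0.0541). This cut does not match strength. The 40 shared peaks had a median rank of 31, and 36 of them were among the 100 strongest replicate 2 peaks. X held 30% of those 100 and 20.5% of the 200 strongest, so part of its difference may follow rank.

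**Figure D3:**
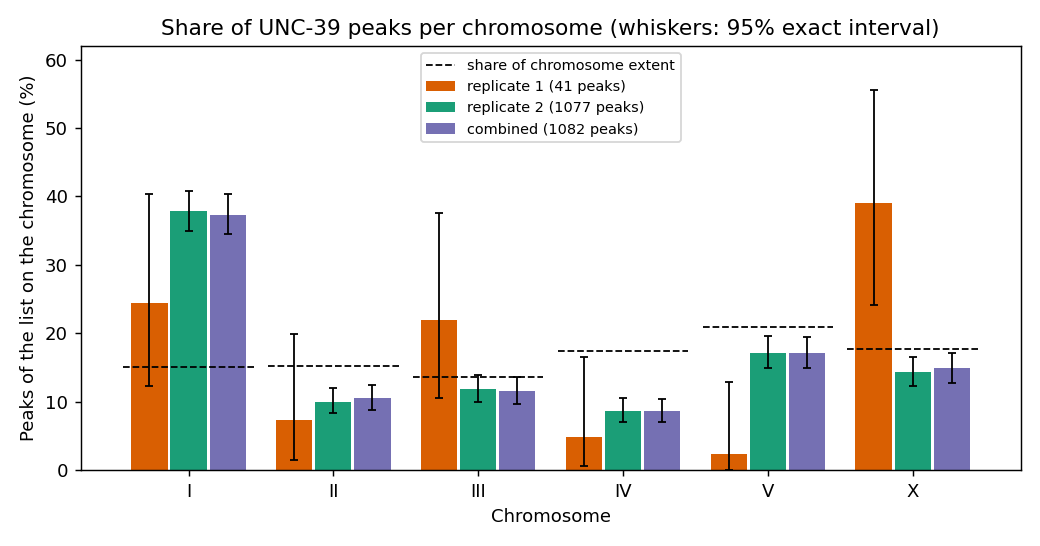
Share of each list's peaks on each chromosome (y axis, percent) for replicate 1, replicate 2 and the combined list, with 95% exact intervals as whiskers and the share of chromosome extent as dashed lines. Chromosome I stands at 37.3% in the combined list, and X at 39.0% of the 41 replicate 1 peaks and 14.3% of the 1077 replicate 2 peaks. The 41 strongest replicate 2 peaks, of which X held 31.7%, are not drawn.

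Position along the chromosomes was compared next. The central 50% of the chromosomes held 543 of 1082 combined peaks (50.2%, interval 47.2 to 53.2%), and a difference from an even spread did not pass the test (exact binomial test, p = 0.927). The same exact test did not pass in replicate 1 (46.3%, interval 30.7 to 62.6%, p = 0.755) or in replicate 2 (50.1%, interval 47.1 to 53.2%, p = 0.951). No chromosome passed the exact test by itself, with shares from 45.96% on X to 52.7% on IV and adjusted p = 1.0 for each.

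Called peaks lay closer together than random placement would put them. The median distance from a combined peak to the next was 45.6 kb, against 51.7 kb in random placements, 95% of which fell between 48.4 and 55.3 kb (two-sided permutation test, p = 0.0008). Of neighbouring pairs, 139 were less than 5000 bp apart, against a median of 78 (two-sided permutation test, p = 0.0002, the smallest p possible). With chromosome I left out, 66 pairs remained under this distance, against a median of 27 (two-sided permutation test, p = 0.0002, the smallest p possible). In replicate 1 the median distance did not pass the test (1136 kb against 955 kb, permutation p = 0.291). It held 3 such pairs, where 95% of placements gave between 0 and 1 (permutation p = 0.0008). These were I 5312792 to 5313575 with I 5315910 to 5316881, I 9380052 to 9380537 with I 9380931 to 9381974, and III 1920965 to 1921690 with III 1923277 to 1923912. The distance of 5000 bp was chosen after the data were seen. Merging peaks within 1000 bp reduced the combined list from 1082 to 1042 peaks. Part of the excess of close pairs may therefore come from single sites split into several calls. Distances were not tested after merging, so these tests describe called peaks and cannot show that separate binding sites cluster.

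**Figure D4:**
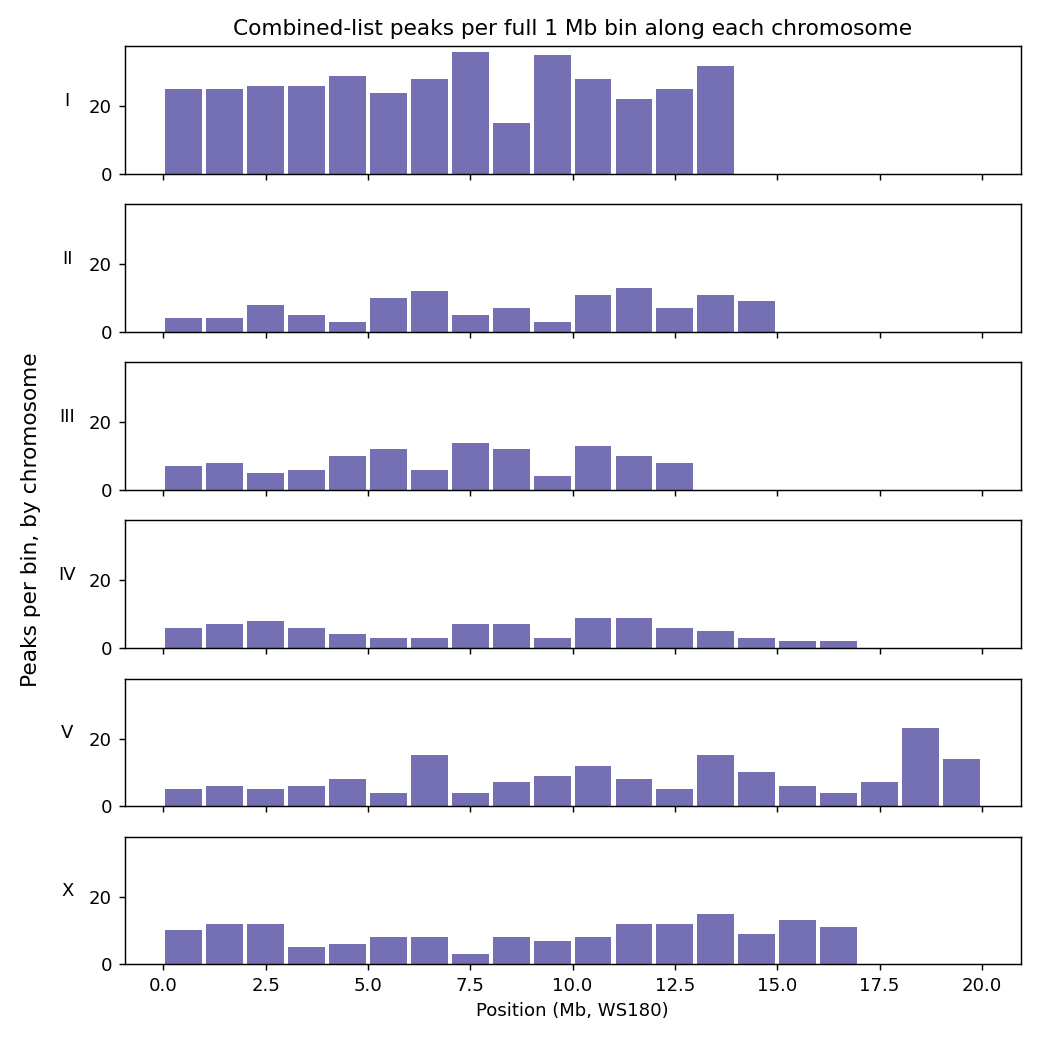
Number of combined peaks (y axis) in each full 1 Mb bin along the 6 chromosomes (x axis, position in Mb, WS180). Chromosome I holds 15 to 36 peaks in every bin, and the bins of the other 5 hold 2 to 23.

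Strong and weak combined sites were compared for position. Chromosome X held 80 of the 541 peaks of lower q (14.8%) and 81 of the 541 of higher q (14.97%), a difference of -0.18 percentage points (Fisher's exact test, adjusted p = 1.0). Chromosome I held 39.9% and 34.8% (Fisher's exact test, adjusted p = 0.359), and the central 50% of chromosomes held 50.6% and 49.7% (adjusted p = 1.0). None of these differences passed the test.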

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

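Of 43 alternative values for 11 results, 29 kept their direction and their side of the threshold or stayed within the interval. Another 8 changed direction, 3 kept their direction but no longer passed the test, and 3 moved outside the interval. The 29 include the values from replicate 2 in place of the combined list. As 1039 of 1082 combined peaks overlapped replicate 2, that agreement was largely fixed beforehand and is no independent support. The overlap of replicate 1 with replicate 2 passed the permutation test under every setting run, at 87.8% when at least 50% of both peaks had to overlap. The overlap of the combined list with replicate 2 was 94.6% under that criterion and 99.1% in the 541 combined peaks of lowest q, and the overlap with replicate 1 was 7.39% in those 541. Using each replicate list instead of the combined list gave 24.4 to 37.9% on chromosome I, 14.3 to 39.0% on X, 46.3 to 50.1% in chromosome centres, and 0.89 to 1.19 for the median distance relative to random placement. The values that stood apart, 24.4%, 39.0%, 46.3% and 1.19, were those of the 41 replicate 1 peaks. Of these, 39.0%, 46.3% and 1.19 lay on the other side of expectation from the main result. The share on X was the least stable: it was 14.8% (exact p = 0.0719) in the 541 peaks of lowest q and 15.2% (exact p = 0.117) at a q threshold 10 times stricter, so the deficit no longer passed the test. The 14.9% on X lay above the 13.7% of protein-coding genes there, the 41 strongest replicate 2 peaks gave 31.7%, and leaving out chromosome I gave 23.7%, each above expectation. The centre share without chromosome I was 49.3%, and the difference on X between the upper 270 peaks and the rest was 1.39 points. Neither passed a test, and beyond the smaller list, the cause of these changes was not tested. In all, 13 of the 43 were chosen after seeing the data: 10 times stricter q, the 41 strongest peaks, the gene share, the removal of chromosome I or of peaks under 50 bp, pairs under 5000 bp, and replicate 2 limited to the largest q of replicate 1. Planned tests of promoters, gene features, gene lists and motifs were not run, as they need WS180 gene positions or sequence. No paired analysis was possible because no values of the input libraries were analysed here, so no group was compared with another. With depth unknown, the absence of a site from the 41 replicate 1 peaks does not show that it was unbound.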

Other observations

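Chromosome X was enriched among the strongest 50 and 100 sites, but not in the wider splits planned beforehand. X held 30 of the 100 strongest combined peaks (30%, interval 21.2 to 39.98%) and 131 of the other 982 (13.3%, interval 11.3 to 15.6%, two-sided Fisher's exact test, adjusted p = 0.00027 over 6 tests). It held 16 of the 50 strongest (32%, Fisher's exact test, adjusted p = 0.00488) and 41 of the 200 strongest (20.5% against 13.6% of the rest, adjusted p = 0.0312). The call at 200 rests on the first 100, since the next 100 held 11 peaks on X (11%, interval 5.62 to 18.8%). In the same splits no difference on chromosome I passed the test, with shares of 32%, 32% and 40.5% of the 50, 100 and 200 strongest, with adjusted p of 0.398 or more. In the planned splits X held 14.8% of the upper 541 peaks against 14.97% of the lower 541 (Fisher's exact test, p = 1.0) and 15.9% of the upper 270 against 14.5% of the rest (Fisher's exact test, p = 0.622). These sets overlap each other, and 27 of the 50 strongest replicate 2 peaks are also in replicate 1.

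Peaks gathered toward the right end of chromosome V, where 49 of its 185 combined peaks (26.5%) lay beyond 18 Mb of its 20.78 Mb extent. The bin from 18 to 19 Mb held 23, against a median of 7 per bin on V, and random placements gave a highest bin of 14.9 on average (permutation p = 0.00090). Several replicate 2 peaks in this bin were far wider than that list's median of 299 bp and lay close to a neighbour. The placements counted each call as a separate peak, so pieces of a broad region would raise the count. The bin was not tested with close peaks merged. Beyond 18 Mb, replicate 2 had 47 peaks and replicate 1 had 0, having only 1 on V.

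In the paragraphs on chromosome I, the wide interval and the combined list, the tests of even spread, of the replicate 1 share, of width against strength and of recovery in replicate 1 were chosen after the results were seen. So were the test of bunching on chromosome V and the comparisons of the 50, 100 and 200 strongest peaks.

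Chromosome I carried 37.3% of combined peaks. Its 14.4% of protein-coding genes lies far below the interval of 34.4 to 40.3%, and the share was 39.7% (interval 35.5 to 43.9%) at a q threshold 10 times stricter, which argues against gene content and against a looser threshold there. The excess was spread along the chromosome, with 14 of 14 full bins of 1 Mb above the median bin of the other chromosomes. The median bin held 26 peaks on I and 7 on the others, so a widespread excess from any source would give this count. It cannot tell a chromosome-wide offset in how ChIP and control reads were scaled from denser UNC-39 binding along I. A difference in copies of the chromosome between libraries would give the same spread and was not tested. Whether UNC-39 binds more often on I stays open, because the replicate 1 share of 24.4% has an interval of 12.4 to 40.3% that includes both the expected 15.1% and the combined share. Whether the excess belongs to the replicate 2 library also stays open: down to rank 173, I held 25% of the 40 peaks found in replicate 1 and 44.4% of the 133 others (Fisher's exact test, adjusted p = 0.0818). Strength was not matched in this comparison, as the 40 had a median rank of 31.

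The 23627 bp interval on chromosome V stood apart in width. Strong peaks were wider, with a median of 846 bp for the other peaks among the 50 strongest against 301 bp for the whole list. The widest of those others was only 3198 bp, which argues against this growth as the explanation of the interval. A candidate explanation is extra DNA copies of the tagged gene in strain OP186, whose transgene carries unc-39, a chromosome V gene in the RefSeq table. This stays open: WS180 gene positions were not used, input DNA of the strain would carry the same copies, and the absence from replicate 1 decides nothing because only 13 of the 20 strongest combined peaks were found there. Broad binding by UNC-39 was not tested.

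The combined list was close to replicate 2 but not identical, with 132 of 1039 overlapping pairs differing in q, 211 differing in coordinates, 43 peaks in neither replicate list and 38 replicate 2 peaks left out. Had its q values been computed on pooled reads of both ChIP libraries, they should differ from those of replicate 2 where both libraries have a peak, yet 35 of the 40 such peaks carried exactly the replicate 2 q and 0 carried the replicate 1 q. This argues against pooled reads for these q values and is consistent with q values computed on the reads of replicate 2. What produced the pairs and peaks that differ stays open. No biological explanation was tested for this pattern.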
